A study of Mus musculus with 6 samples.

How the data were processed

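Gene expression was measured in the livers of 6 male C57BL/6 mice, 1 Affymetrix array per mouse. Per the labels, 3 livers expressed green fluorescent protein (GFP, mice 13, 21 and 6) and 3 expressed Sonic Hedgehog (SHH, mice 26, 28 and 31). The series' design text names hydrodynamic transfection, the rapid injection of DNA in a large volume so that hepatocytes take it up, as the way the genes were brought into the liver. Total RNA was extracted with Trizol and labelled with biotin, per the labels' protocols. The labels give no batch, day or litter, and the mouse numbers are not shared between the groups, so no pairing was used. They do not state the age of the mice or the species of the SHH sequence.

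The deposited values are log2 signals, 1 column per array. Per the submitters' processing notes they were made with RMA, which corrects the background, makes the distributions of the arrays equal and summarises the probes of each probe set. The version, the probe set level and the annotation are not given in the sources used here. The values were read as log2 because each array ran from near 0.5 to near 14. The table held 41345 probe sets. Platform annotation paired 25335 of them with genes, of which 23521 named 1 gene and 1814 named several, and 16010 were unnamed here. Symbols were compared with a RefSeq table of assembly GRCm38.p6 through gene identifiers. This changed 0 symbols, and 193 probe sets naming 1 gene had no entry in that table. No coordinates were used. In all, 1395 probe sets held the same values as another probe set.

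For each gene, the probe set naming that gene alone with the highest mean over the 6 arrays was used, which gave 22180 genes, none of them with values identical to another gene's. There were 1082 genes with more than 1 such probe set. SHH and GFP livers were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the values as deposited, with no filter on level and no covariate. The Benjamini-Hochberg threshold was 0.05 over all genes. Spreads are SD over 3 mice and intervals are 95% intervals from the same fit. Fold changes are 2 to the power of the difference of mean log2 signals, and array signals tend to understate the change of dim genes. An exact permutation test of 3 mice against 3 cannot go below p = 0.1, so single genes were tested only with the limma model, which borrows information on the spread across genes. The number of arrays limits the precision.

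Fixed gene lists, 36 of them with 965 genes, of which 871 were measured, were tested with camera in limma at its preset correlation of 0.01 between genes, which compares each list with all other genes, with Benjamini-Hochberg adjustment over the 36 lists. The same lists were tested with camera at a correlation estimated per list, with camera on ranks, and with fry, which asks whether the genes of a list move one way without comparing them with other genes. Counts of list members past the threshold are given adjusted over all genes and adjusted over the list alone. The groups, the tests, the lists, the alternatives and the rule for naming genes were chosen before the data were examined.

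The rule named 22 genes in every case, Shh first, of which 20 were measured; the other 2 were not analysed here. It further named up to 15 genes per direction past the threshold or, where fewer passed, up to 8 per direction by the smallest unadjusted p, leaving out predicted genes, and up to 4 members per list, taking first those past the threshold adjusted over the list alone. Genes named outside this rule are said to be so.

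The alternatives were the mean of all probe sets of a gene, the probe set with the largest interquartile range, only genes above the median level, a second quantile normalization, equal array medians, a trended or robust prior in eBayes, array weights, every probe set tested on its own, a minimum change of 1 on the log2 scale, a threshold of 0.1, the other list tests, and each mouse left out in turn.

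The scripts were tested on simulated data for the SHH against GFP comparison, with 22180 genes, 200 of them changed, in 10 runs. With noise drawn from each gene's own moderated variance, 91.6% of genes changed by 1 on the log2 scale and 100% of those changed by 2 or more were recovered, but 7.20% of calls were false, above the 5% the threshold names. A second simulation was added after that excess was seen, with variances drawn from the fitted prior. It recovered 75.6% at a change of 1 and 99.2% at a change of 2, with 4.49% of calls false. Lists of 25 unchanged genes had camera p under 0.05 in 3.25% and 1.75% of cases in the first and second simulation. Lists shifted by 0.3 were recovered in 100% of cases in both. The simulated genes were independent, so these shares do not cover lists whose genes move together between mice. Each simulated change was also the same in every SHH array. The shares of recovered genes therefore do not cover genes that change unevenly between mice. In the data Mt2 and Lcn2 differed by 4.30 and 3.59 on the log2 scale, with SDs of 2.14 and 2.51 in SHH livers, and did not pass.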

Results

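Expression arrays of 6 mouse livers were compared, 3 expressing GFP and 3 expressing Sonic Hedgehog (SHH), the secreted ligand that starts Hedgehog signalling. The design asked how SHH in the liver affects fibrosis and the expression of genes related to it. Each array gave 41345 log2 signals, with medians between 4.32 and 4.40. Pearson correlations over probe sets were 0.975 to 0.980 among GFP livers, 0.976 to 0.979 among SHH livers and 0.971 to 0.981 between the groups, so the ranges overlapped. The highest values were those of SHH 26 with GFP 6 (0.9807) and GFP 21 (0.9804). They lay above those of SHH 26 with SHH 28 (0.9791) and SHH 31 (0.9775).

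Shh signal was higher in each SHH liver than in any GFP liver. It was 3.43, 3.67 and 3.86 in GFP mice 13, 21 and 6, and 4.57, 4.28 and 4.63 in SHH mice 26, 28 and 31. The difference of 0.84 on the log2 scale (1.79-fold) had a 95% interval of 0.48 to 1.19. It did not pass the threshold over all genes (limma, adjusted p = 0.356). The GFP values and that of SHH 28 lay below their arrays' median signal, those of SHH 26 and SHH 31 above it (4.33 and 4.40). The labels do not say whether the introduced sequence matches the probes.

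Hhip, a membrane protein that binds Hedgehog ligands and is itself induced by the pathway, had the smallest unadjusted p of all genes. Its log2 signal was 5.38 ± 0.08 (SD, n = 3) in GFP livers and 6.77 ± 0.27 (SD, n = 3) in SHH livers, 2.62-fold higher. Ccnd1, which encodes cyclin D1, was 2.15-fold higher (6.17 ± 0.32 against 7.27 ± 0.64, SD, n = 3), and highest in SHH 31 at 7.96. Over all genes neither passed in limma, with adjusted p = 0.174 for Hhip and 0.490 for Ccnd1; adjusted over the list alone, both rose. Without SHH 26, Hhip passed over all genes (adjusted p = 0.0349). The classical pathway readouts Gli1 and Ptch1 differed by -0.00 and 0.03 on the log2 scale, with 95% intervals of -0.32 to 0.31 and -0.26 to 0.32. The transcription factors Gli2 and Gli3 differed by -0.25 and 0.04. Gli1 (3.41 to 3.76), Gli2 and Gli3 lay below the median signal of every array (4.32 to 4.40), where array signals tend to understate a change. The small differences of Gli1 and Gli3 therefore say little, while Ptch1 lay above the medians (6.85 to 7.12). The signal transducer Smo differed by 0.22, with 6.33, 6.09 and 5.86 in SHH mice 26, 28 and 31 against 5.65 to 6.03 in GFP livers.

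Of 15 measured Hedgehog target genes, 10 had higher means in SHH livers, 2 passed upward adjusted over the list alone (Hhip and Ccnd1), 0 passed downward and 13 did not pass. The count of 2 became 1 without GFP 13, GFP 21 or SHH 31. Foxf1, a mesenchymal transcription factor, was 1.40-fold higher and did not pass. The list as a whole was shifted upward by camera at the preset correlation (adjusted p = 0.0327), but not with an estimated correlation (adjusted p = 0.273). The call was lost without GFP 6 (adjusted p = 0.0919), SHH 26 (0.0892) or SHH 31 (0.133). It was also lost with the mean of all probe sets (0.0701), the probe set with the largest interquartile range (0.0977), only genes above the median level (0.0658), a second quantile normalization (0.0540) and ranks (0.170). Of 25 genes for Hedgehog ligands, receptors and transducers, 9 had higher and 16 lower means, 0 passed either way, and the list was not shifted (camera, adjusted p = 0.515).

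**Figure D1:**
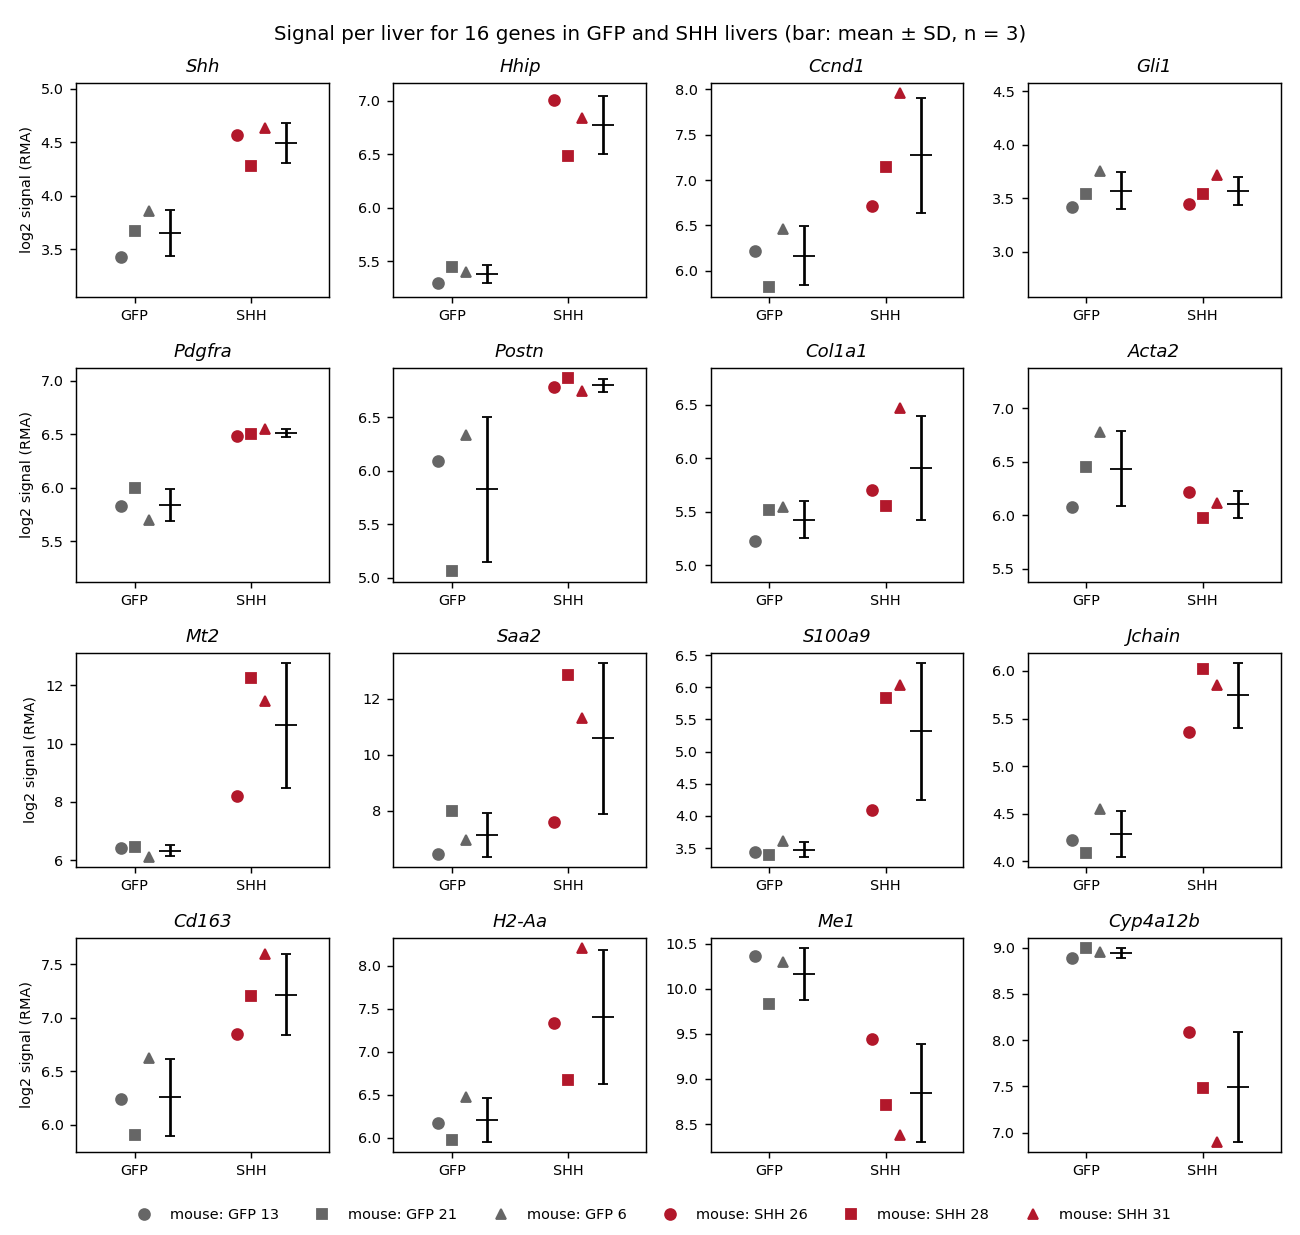
Log2 signal (RMA, vertical axes, each spanning at least 2 units) of 16 genes in 3 GFP livers (grey) and 3 SHH livers (red), 1 symbol per mouse, with bars for mean and SD. Hhip lies between 6.48 and 7.00 in the SHH livers against 5.29 to 5.45 in the GFP livers, while Gli1 overlaps and Mt2 runs from 8.21 in SHH 26 to 12.24 in SHH 28.

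No single gene passed the threshold over all 22180 genes. Limma called 0 genes higher and 0 lower, with 738 higher and 889 lower at an unadjusted p under 0.05, where 1109 in all are expected by chance. The other gene-level settings also called 0, except that leaving out SHH 26 gave 30 higher and 16 lower genes. Those included the metallothionein Mt2 (5.51 on the log2 scale without that mouse), Orm2 (4.59), the neutrophil gene S100a9 (2.46) and Hhip (1.28). The median difference of all genes was -0.03.

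The smallest unadjusted p values upward, none past the threshold over all genes, belonged to Hhip, the immunoglobulin genes Igh-VS107 (2.50-fold higher), a kappa variable segment (10.3-fold) and Jchain (2.74-fold), the macrophage pore protein gene Mpeg1 (2.72-fold), Rdh16f2 (1.98-fold), Jade2 (1.83-fold) and Fbxw17 (1.63-fold). The kappa segment belongs to a family of near-identical segments, so its signal is uncertain. Downward they were Acss3 (2.10-fold lower), the matricellular gene Ccn1 (2.16-fold), Shisa9 (1.73-fold), the peroxisomal thiolase Acaa1b (2.11-fold), Tsc22d1 (2.28-fold), the cytochrome P450 Cyp4a12b (2.74-fold), Zfp982 (2.13-fold) and Lrrc6 (1.63-fold). The Lrrc6 values (2.04 to 2.95) lay below the lower quartile of every array (3.13 to 3.22), so its fall says little.

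Genes of fibrosis gave a mixed picture. Col1a1, a chain of the main fibrillar collagen, was 5.43 ± 0.18 (SD, n = 3) in GFP livers and 5.91 ± 0.49 (SD, n = 3) in SHH livers, a difference of 0.48 (SE 0.23; limma, adjusted p = 0.707) that became 0.20 without SHH 31. Col1a2 and Col3a1 differed by 0.11 and 0.14, and without SHH 31 these became -0.09 and -0.20. Acta2, the smooth muscle actin of activated stellate cells, differed by -0.33 (95% interval -0.75 to 0.08), and by -0.51 and -0.17 without GFP 13 and GFP 6. The collagenase inhibitor Timp1 differed by -0.13, with 2.365 to 2.748 in GFP livers, highest in GFP 21, and 2.336 to 2.588 in SHH livers. Those values lay below the lower quartile of every array (3.13 to 3.22), so they say little. Tgfb1 differed by 0.04, and the filament and receptor genes Des, Vim and Pdgfrb by 0.16, 0.40 and 0.02, with Vim at 0.15 without SHH 31. None of these genes passed in limma over all genes.

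Of 43 extracellular matrix genes, 32 had higher means in SHH livers, and 0 passed over all genes or adjusted over the list alone, where 1 passed upward without GFP 21 and 2 without SHH 28. The members with the smallest p were the proteoglycan Lum (1.62-fold higher), the matricellular gene Postn (1.96-fold), Tnc (1.62-fold) and Col14a1 (1.43-fold). Camera at the preset correlation placed the list above other genes (adjusted p = 2.56e-06), with adjusted p = 0.258 with an estimated correlation. Mean shifts were 0.157, 0.058 and 0.346 in SHH mice 26, 28 and 31, and without SHH 31 the adjusted p was 0.0251 and the mean difference 0.107 in place of 0.187.

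Of 28 myofibroblast genes, 17 had higher means and only the growth factor receptor Pdgfra rose adjusted over the list alone (1.59-fold, 6.48 to 6.55 in the SHH livers against 5.69 to 5.99). Fap was 1.23-fold higher, Gfap 1.36-fold and Ddah1 1.57-fold lower, and none of these 3 passed. The count of 1 upward became 0 without GFP 6, SHH 28 or SHH 31, and 1 gene passed downward without GFP 13 or SHH 26. Camera gave adjusted p = 0.0337 for the list at the preset correlation and adjusted p = 0.258 with an estimated correlation. The call was lost without GFP 13 (adjusted p = 0.200), SHH 28 (0.0636) or SHH 31 (0.246, with the mean at 0.038 in place of 0.092), and with only genes above the median level (0.0769), a second quantile normalization (0.0692) or array weights (0.113).

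Other lists tied to fibrosis were not shifted by camera at the preset correlation. Matrix remodelling genes (adjusted p = 0.0626; Mmp14 1.60-fold higher, Timp3 1.52-fold lower), resting stellate cell genes (0.217; Colec10 1.45-fold higher), TGF-beta signalling genes (0.515; Inhba 1.35-fold higher, Inhbe 1.63-fold lower) and genes of epithelial to mesenchymal transition (0.894; Prrx1 1.38-fold lower) had 0 members past the threshold adjusted over the list alone. For the last 2 lists the mean was negative (-0.01 and -0.02) while camera pointed upward. Without SHH 28 the resting stellate cell list passed (adjusted p = 0.0296), and without GFP 6, SHH 26 or SHH 28 so did matrix remodelling (0.0358, 0.00570 and 0.0135). Adjusted over the list alone, 2 remodelling genes passed upward without SHH 26 and 1 TGF-beta gene downward without GFP 13. Camera pointed downward for the transition genes without GFP 13, GFP 6 or SHH 26, and for the TGF-beta genes without SHH 31.

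The acute phase genes, which the liver makes in response to inflammation, had the largest mean shift of the 36 lists. Of 26 measured, 25 had higher means in SHH livers and 22 rose adjusted over the list alone, although 0 passed over all genes. Mt2 was 19.7-fold higher, and on the log2 scale the differences were 4.30 for Mt2, 3.59 for the iron-binding lipocalin Lcn2, 3.46 for serum amyloid Saa2 and 3.23 for Orm2. The mean shift of the list was 0.452 in SHH 26, 2.03 in SHH 28 and 1.51 in SHH 31. Mt2 reached 8.21, 12.24 and 11.45 in these mice, against 6.11 to 6.45 in GFP livers, while Saa2 in SHH 26 (7.60) lay above GFP 6 (6.95) and below GFP 21. Camera gave adjusted p = 8.68e-26 at the preset correlation and adjusted p = 0.258 with an estimated correlation. The count of 22 fell to 6 without GFP 13 or GFP 6 and to 7 without SHH 28 or SHH 31, and the Saa, Orm and metallothionein genes have close relatives that can share signal.

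Of the 5 lists of immune cell markers, all were called higher in SHH livers by camera at the preset correlation and none with an estimated correlation (adjusted p = 0.258 for each). All 16 neutrophil genes had higher means and 4 rose adjusted over the list alone: S100a9 (3.59-fold), Retnlg (2.92-fold), S100a8 (2.83-fold) and Cxcr2 (1.82-fold). Of 25 genes of monocytes and monocyte-derived cells, 22 had higher means and 6 rose adjusted over the list alone, among them the antigen presentation genes H2-Ab1 (2.33-fold), H2-Aa (2.30-fold) and H2-Eb1 (2.08-fold) and the chemokine receptor Ccr2 (1.95-fold). Of 21 Kupffer cell and macrophage genes, 20 had higher means and 0 passed adjusted over the list alone; Cd163 was 1.95-fold and Adgre1 1.78-fold higher. Among 18 B and plasma cell genes, Jchain and Ighm (2.61-fold) rose and 16 did not pass. Of 22 T and natural killer cell genes, 17 had higher means and 0 passed (Cd3g 2.03-fold higher).

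Camera at the preset correlation called these 5 lists higher, with adjusted p = 4.66e-10 for neutrophils, 3.98e-11 for monocyte-derived cells, 3.20e-10 for macrophages, 6.16e-04 for B and plasma cells and 1.08e-06 for T and natural killer cells. With an estimated correlation each had adjusted p = 0.258. GFP 6 had a macrophage mean shift of 0.445, above the 0.263 and 0.278 of SHH 26 and SHH 28, and the macrophage count of 0 became 12 without GFP 6 and 6 without SHH 26. The neutrophil count of 4 became 0 without SHH 31 and 11 without SHH 26, and the monocyte count of 6 became 3, 0 and 14 without GFP 13, GFP 21 and SHH 26. The count of T and natural killer cell genes became 4 without SHH 28. Without SHH 31 the mean difference went from 0.336 to 0.152 for T and natural killer cell genes, from 0.516 to 0.270 for macrophages and from 0.534 to 0.297 for monocyte-derived cells. The T and natural killer cell mean was 0.277, 0.026 and 0.704 in SHH mice 26, 28 and 31, against 0.086 in GFP 21.

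Interferon-induced genes had higher means for 27 of 28 members, and 0 passed adjusted over the list alone (Gbp3 2.05-fold, Mx2 1.55-fold higher). Of 30 genes of inflammatory mediators, 23 had higher means and Il1b rose (2.72-fold). Camera at the preset correlation gave adjusted p = 1.43e-09 and 3.99e-05, and each list had adjusted p = 0.258 with an estimated correlation. The count of 1 mediator became 0 without GFP 13, GFP 21 or SHH 28, 2 without GFP 6 and 7 without SHH 26, and that of interferon genes 5 without SHH 28. Without SHH 31 the mean difference went from 0.371 to 0.202 for interferon genes and from 0.319 to 0.175 for mediators.

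Camera at the preset correlation called 5 lists of hepatocyte metabolism lower in SHH livers, and with an estimated correlation it called none of them (adjusted p = 0.332 for cholesterol synthesis and 0.258 for the others). Of 27 fatty acid oxidation genes, 24 had lower means and 2 fell adjusted over the list alone, Acaa1b (2.11-fold lower) and Cyp4a31 (1.69-fold), while the regulator Ppara was 1.48-fold lower and did not pass. Of 29 lipogenesis genes, 23 had lower means and Me1, an NADPH-producing enzyme, fell (2.49-fold lower); Acss2 was 1.67-fold lower and did not pass. The 20 cholesterol synthesis genes included targets of the regulator SREBP2. Of these 20, 18 had lower means and 0 passed (Rdh11 1.47-fold, Msmo1 1.37-fold lower). Among 33 drug metabolism genes 26 had lower means and 0 passed (Ugt2b36 1.45-fold, Ephx1 1.37-fold lower). Of 29 bile acid genes, 21 had lower means and 0 passed; Cyp8b1, the sterol 12-alpha-hydroxylase, was 2.12-fold lower.

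Camera at the preset correlation gave adjusted p = 1.02e-07 for fatty acid oxidation, 1.40e-06 for lipogenesis, 1.72e-05 for cholesterol synthesis, 1.09e-04 for drug metabolism and 0.00867 for bile acids. With an estimated correlation these were adjusted p = 0.332 for cholesterol synthesis and 0.258 for each of the others. The bile acid call was lost without GFP 6 (adjusted p = 0.0822), SHH 28 (0.0518) or SHH 31 (0.0946). Adjusted over the list alone, the count of 1 lipogenesis gene became 0 without GFP 13 or SHH 31, 2 without SHH 26, 3 without SHH 28 and 9 without GFP 21. That of 2 oxidation genes became 1 without GFP 13, GFP 6 or SHH 31 and 7 without SHH 26, where 9 drug metabolism and 3 bile acid genes also passed downward and 1 bile acid gene upward. The cholesterol synthesis mean was -0.241, -0.025 and -0.517 in SHH mice 26, 28 and 31, against -0.066 in GFP 21, and the difference of -0.261 became -0.133 without SHH 31.

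Male-biased liver genes were lower, with 19 of 23 means below those of GFP livers and 3 that fell adjusted over the list alone: Cyp4a12b (2.74-fold), Cyp4a12a (2.38-fold) and Cyp2u1 (2.04-fold). The mean shift was -0.370, -0.386 and -1.07 in SHH mice 26, 28 and 31. Camera gave adjusted p = 3.20e-06 at the preset correlation and adjusted p = 0.258 with an estimated correlation. Of 22 female-biased genes, Cyp2b9 (2.62-fold) and Atp6v0d2 (1.94-fold) rose adjusted over the list alone, but the list was not shifted (camera, adjusted p = 0.594), with a median of -0.12 and a mean of 0.10. Cyp4a12a and Cyp4a12b are close paralogs whose signals may be shared. Without SHH 31 the male-biased mean difference went from -0.607 to -0.378. The count of 3 male-biased genes became 10 without SHH 26 (with 1 upward), 6 without SHH 28, 1 without GFP 21 and 2 without GFP 13, GFP 6 or SHH 31. That of 2 female-biased genes became 0 without SHH 28 or SHH 31, 1 without GFP 13 or GFP 21, and 3 without GFP 6 or SHH 26.

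Genes of hepatocytes near the central vein had lower means for 20 of 22 members, with 0 past the threshold adjusted over the list alone (Cyp1a2 1.28-fold lower). The list was lower by camera at the preset correlation (adjusted p = 0.00755), with adjusted p = 0.258 with an estimated correlation, and it was the 1 list called by fry (adjusted p = 0.0275). Near the portal vein, 14 of 20 genes had higher means, the protease gene Ctsc rose (1.99-fold) and the list was not shifted (camera, adjusted p = 0.0964). The Ctsc call was lost without GFP 13, GFP 6, SHH 28 or SHH 31, and 1 gene of that list passed downward without GFP 21. Secreted proteins and other functions of hepatocytes were not shifted (camera, adjusted p = 0.594), and 0 of 30 members passed. Alb, the albumin gene, was 13.68 ± 0.02 in GFP and 13.69 ± 0.03 in SHH livers (SD, n = 3), but it is the highest signal on every array, a value that the quantile normalization in RMA holds alike across arrays, so these values do not show whether it differed.

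Cell cycle genes had higher means for 26 of 34 members and 0 passed (Mcm6 1.41-fold, Plk1 1.38-fold higher). Camera at the preset correlation gave adjusted p = 2.55e-04, and adjusted p = 0.388 with an estimated correlation. The mean shift was 0.004, 0.003 and 0.440 in SHH mice 26, 28 and 31, and without SHH 31 the call was lost (adjusted p = 0.491, mean difference 0.003 in place of 0.149). Among 21 p53 target genes 15 had higher means and 0 passed (Btg2 2.32-fold, the cell cycle inhibitor Cdkn1a 2.22-fold higher); the list had adjusted p = 0.0146 at the preset correlation and adjusted p = 0.258 with an estimated correlation. That call was lost without GFP 6 (adjusted p = 0.152) or SHH 31 (0.0654) and with only genes above the median level (0.0658), and 2 genes passed upward adjusted over the list alone without SHH 26.

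Fetal and tumour genes of the liver were not shifted (camera, adjusted p = 0.515, pointing downward without GFP 21 or SHH 31). Of 26, Ccnd1 and the adhesion receptor Cd44 (1.70-fold) rose and Ccn1 fell adjusted over the list alone. The count of 2 upward became 0 without GFP 13, GFP 21 or SHH 31, 1 without SHH 28 and 3 without GFP 6, while the count downward was 1 whichever mouse was left out. The fetal gene Afp differed by -0.07 on the log2 scale. Bile duct and progenitor genes were not shifted (camera, adjusted p = 0.0634), and Krt19 differed by -0.03; that list passed with a trended prior (0.0453) and among genes above the median level (0.00544), and without GFP 6 (0.0312) or SHH 26 (0.0167). Clock genes were called lower at the preset correlation (adjusted p = 0.0443), with adjusted p = 0.388 with an estimated correlation. Of 19 clock genes Noct fell adjusted over the list alone (2.14-fold lower), and Dbp was 1.54-fold lower; the count of 1 became 0 without SHH 28 or SHH 31, 2 without SHH 26 and 4 without GFP 21. The clock call was lost without GFP 13 (0.200, with the mean at -0.079 in place of -0.19), SHH 28 (0.189) or SHH 31 (0.242), with the mean of all probe sets (0.0537), array weights (0.127) and ranks (0.112).

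Lists for other sources of signal were not shifted by camera at the preset correlation. Endothelial genes had lower means for 21 of 27 members (adjusted p = 0.0888). Dnase1l3 differed by -0.59 on the log2 scale, with 7.23, 6.51 and 7.80 in SHH mice 26, 28 and 31 against 7.47 to 8.14 in GFP livers. The endothelial list passed by camera without GFP 21 (adjusted p = 0.00689) or SHH 31 (5.09e-05) and with array weights (0.00333), while camera pointed upward without SHH 28. Stress response genes (adjusted p = 0.316; Creld2 1.75-fold higher), erythroid genes (0.527; Car1 1.60-fold lower), mesothelial genes (0.199; Krt14 1.34-fold lower) and pancreas, fat and muscle genes (0.206; Car3 1.61-fold lower) had 0 members past the threshold adjusted over the list alone. Without SHH 26, 1 erythroid gene and 1 of the pancreas, fat and muscle genes passed downward and 1 mesothelial gene upward, and without GFP 6, 1 stress gene upward. Without SHH 28 camera pointed downward for the stress genes and for the pancreas, fat and muscle genes. The last list had a mean shift of 0.427 in SHH 28, where the muscle genes Acta1, Tnnt3 and Myh4, the first pair named after their values were seen, were 3.90-fold, 3.83-fold and 3.74-fold above the mean of the other livers, and between -0.066 and 0.058 in the other 5 livers. Over all 36 lists, camera at the preset correlation called 13 higher and 8 lower, and with an estimated correlation 0 and 0. Fry for genes moving one way called 0 higher and 1 lower. Fry for change in either direction passed Hedgehog targets (adjusted p = 0.00415) and fetal and tumour genes (0.00721). It also passed lipogenesis (0.0179), mesothelial (0.0179), central vein (0.0294), myofibroblast (0.0308) and fatty acid oxidation genes (0.0461). That version gives no direction of shift and does not compare a list with other genes. Another split of the 6 livers, which mixed the groups, also gave 21 lists by camera at the preset correlation.

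**Figure D2:**
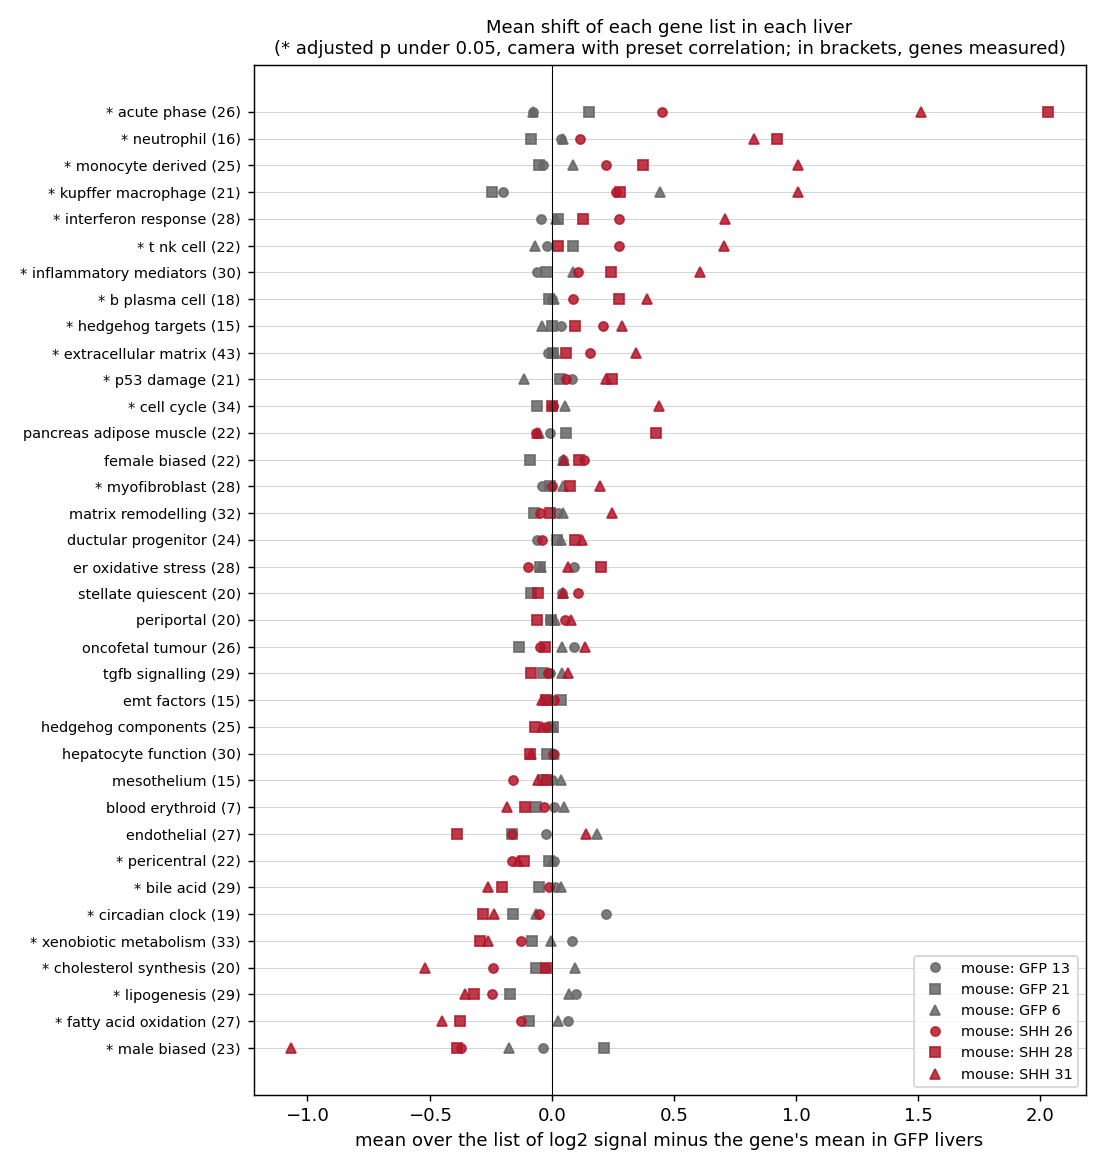
Mean over each of 36 gene lists of the log2 signal minus the gene's mean in GFP livers (horizontal axis, log2 units), 1 symbol per liver, GFP in grey and SHH in red, with stars at lists called by camera at the preset correlation. Acute phase genes lie at 0.452, 1.51 and 2.03 in the SHH livers, and SHH 31 holds the highest macrophage and cell cycle means, 1.01 and 0.440.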

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

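The test of probe sets outside the gene-level comparison was chosen only after the gene-level result was seen. Probe set 17520624, which had no gene name here and so took no part in the comparison, showed a signal above that of the GFP livers. Its log2 signal was 6.88, 6.78 and 6.66 in GFP livers and 8.66, 8.81 and 9.10 in SHH livers, a difference of 2.09 (4.24-fold higher). Limma gave adjusted p = 0.0220 over the 16010 unnamed probe sets and 0.0567 over all probe sets. Probe set 17428882 had the same adjusted p over the unnamed probe sets and was lower in SHH livers, at 1.52, 1.13 and 1.55 against 3.99, 3.81 and 3.59. These SHH values lie far below the lower quartile of their arrays (3.13 to 3.17), so no fold is given. Which transcripts they measure is not known here.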

How the results depend on the processing

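All alternatives here were chosen before the data were examined. With 1 array per mouse and 3 mice per group, single mice set several calls. The count of genes past the threshold was 0 higher and 0 lower in every setting except without SHH 26, where it was 30 and 16; over the mice left out the ranges were 0 to 30 and 0 to 16. The count of lists was 10 to 14 higher and 7 or 8 lower with other settings of the same test, 9 to 14 and 6 to 9 over the mice left out, 0 and 0 with an estimated correlation, and 0 and 1 by fry. Camera has no robust prior, so that alternative was not run for lists. With an estimated correlation many lists shared adjusted p = 0.258 in camera, because the adjustment tied them. Their unadjusted camera p ran from 0.0321 for central vein genes to 0.129 for bile acid genes.

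The acute phase list kept its call in every setting of camera at the preset correlation, with adjusted p from 1.38e-41 to 1.14e-18 over the mice left out, and lost it with an estimated correlation (0.258) and by fry (0.215). The extracellular matrix list did so too, with 2.69e-09 to 0.0251 over the mice left out, 0.258 and 0.282. Hedgehog targets ranged from 0.00561 to 0.133 over the mice left out. They gave 0.0701 with the mean of probe sets, 0.0977 with the largest interquartile range, 0.0658 among genes above the median level, 0.0540 with quantile normalization, 0.170 on ranks, 0.273 with an estimated correlation and 0.223 by fry. Myofibroblast genes ranged from 0.0164 to 0.246 over the mice left out, and gave 0.0769 among genes above the median level, 0.0692 with quantile normalization, 0.113 with array weights, 0.258 with an estimated correlation and 0.282 by fry. The cause was not tested.

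Some directions reversed, all of them for genes and lists not past the threshold. Log2 differences of Gli1 became 0.034 with quantile normalization and 0.018 with equal medians, that of Krt19 0.0096 with quantile normalization, that of Tgfb1 -0.12 with array weights and that of Col1a2 -0.10 at another of its probe sets. Over the mice left out the differences ran from -0.083 to 0.089 for Gli1, -0.014 to 0.12 for Ptch1, -0.091 to 0.25 for Col1a2, -0.20 to 0.41 for Col3a1, -0.20 to 0.25 for Tgfb1, -0.043 to 0.34 for Des, -0.065 to 0.12 for Pdgfrb, -0.11 to 0.068 for Krt19, -0.14 to 0.042 for Afp and -2.97e-04 to 0.027 for Alb. The transition list reversed with the largest interquartile range (adjusted p = 0.964) and by fry (0.432). It also reversed without GFP 13 (0.905), GFP 6 (0.974) or SHH 26 (0.917), with 0.762 to 0.974 over all mice left out. Female-biased genes reversed on ranks (0.771) and by fry (0.982), and Hedgehog components among genes above the median level (0.845). Over mice left out, adjusted p ran from 5.09e-05 to 0.941 for the endothelial list and 0.0972 to 0.920 for stress genes. It ran from 0.297 to 0.975 for fetal and tumour genes and 0.262 to 0.960 for TGF-beta genes. For pancreas, fat and muscle genes it ran from 0.0946 to 0.854. The endothelial list kept its direction at 5.09e-05. Without SHH 28, reversals came in the endothelial list (0.777), stress genes (0.920) and pancreas, fat and muscle genes (0.854). Further reversals came without SHH 31 in TGF-beta genes (0.960) and without GFP 21 or SHH 31 in fetal and tumour genes (0.924 and 0.975). Their cause was not tested. Over all named genes and settings, 1292 values kept direction and side, 23 reversed, 18 newly passed and 0 were lost; for lists these were 481, 14, 11 and 68.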

Other observations

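Tests of lists, scores and explanations in this part were chosen only after the results were seen, except the splits of the livers, the count of separated acute phase genes and the second muscle list, whose bounds were written before their values were seen. Immunoglobulin segment and constant genes were higher in SHH livers: 18 of 20 had higher means and 12 passed adjusted over the list alone. Camera gave adjusted p = 2.17e-17 over 6 added lists at the preset correlation, and adjusted p = 0.0581 with an estimated correlation. The list was chosen after some of its members were seen to be high, so its test is not independent evidence. Of 12 B cell surface genes, most of them dim here, 0 passed (camera, adjusted p = 0.105). The segments share sequence, so single genes among them are uncertain.

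Immediate early genes, which respond within minutes to stimuli and to handling of tissue, had higher means for 15 of 24 members, and 1 passed adjusted over the list alone. Camera gave adjusted p = 0.00221 at the preset correlation and adjusted p = 0.368 with an estimated correlation. Egr1, named after its values were seen, was 6.75, 8.33 and 6.57 in SHH mice 26, 28 and 31, against 5.18 to 5.53 in GFP livers. YAP target genes (adjusted p = 0.889), major urinary protein genes (0.143) and the second list of muscle genes (0.133) were not shifted by camera. Adjusted over the list alone, Ccn1 fell among the YAP targets and Mup21 among the urinary protein genes (-1.34 on the log2 scale), and 0 of the muscle genes passed.

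A split of the 6 livers into 3 and 3 can be made in 10 ways, too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 1627 genes and the highest other 1437, and 1 of the 10 gave as many. Past the adjusted threshold the real split gave 0 and the highest other 0, so 10 of 10 gave as many. For lists called by camera the real split gave 21 and the highest other 21, so 2 of the 10 gave as many. The other such split set GFP 13, GFP 6 and SHH 26 against GFP 21, SHH 28 and SHH 31.

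The higher acute phase genes were weighed against a single mouse and a shift of all genes as sources. In 18 of 26 members every SHH liver lay above every GFP liver, where chance gives 1.3 on average in that direction. That met the bound written beforehand against 1 mouse alone as the source. The members move together (estimated correlation 0.634), so they are not separate evidence, and the average does not measure how unusual 18 is. The list mean was 0.452, 2.03 and 1.51 in SHH mice 26, 28 and 31, against -0.078 to 0.154 in GFP livers. The rise was thus not confined to 1 mouse. A shift of all genes alike would cancel within an array. There the list mean lay above the mean of all other genes by 1.35 (SE 0.47), with every SHH liver above every GFP liver. The rise of the list against other genes and the median difference of all genes (-0.03) were already known. The comparison therefore restates them and adds no support. That median itself shows no shift of all genes as large as that of the list. The difference in the introduced gene, SHH or GFP, and differences between the mice in infection, in handling or in the injections were not tested and stay open. The smaller rise in SHH 26 was not explained.

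The macrophage genes could be higher because fewer hepatocytes were sampled, which would raise the markers of all other cell types alike. The mean of the macrophage list lay above that of the endothelial list by 0.65 (SE 0.18), with every SHH liver above every GFP liver. Both list means, 0.516 and -0.135, were known before this comparison was chosen, so it is no independent test. The macrophage list alone did not separate the groups, with GFP 6 (0.445) above SHH 26 (0.263) and SHH 28 (0.278). There the separation came from the endothelial list, at 0.186, -0.161 and -0.386 in these mice. A larger number of macrophages, more transcript per macrophage and lower endothelial signal were not told apart and stay open.

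Whether SHH 31 alone carries the matrix signal was tested in 2 parts. The matrix list stayed past the threshold without it (camera at the preset correlation, adjusted p = 0.0251), which met the bound against that mouse as the only source. Over all alternatives of that list the adjusted p ranged from 2.69e-09 to 0.282. The test cannot decide the question, because the estimated correlation of the list was 0.205, above the preset 0.01. A split that mixed the groups also gave 21 lists at that preset. Without SHH 31 the mean shift went from 0.187 to 0.107 and the median from 0.145 to 0.073. The list means of SHH 26 and SHH 28 were 0.157 and 0.058, against -0.017 to 0.012 in GFP livers. With an estimated correlation the list is not called even with all mice (camera, adjusted p = 0.258). For Col1a1, Col1a2 and Col3a1 the mean difference was 0.246 (SE 0.284) with all mice and -0.031 without SHH 31. Their mean was 0.076, -0.137 and 0.80 in SHH mice 26, 28 and 31. The bound for a single-mouse source was a value within 1 SD between GFP mice of 0 (SD 0.0259). The value lay just outside it on the lower side, so the test as written gave no decision. Averaged over the 3 genes, SHH 26 and SHH 28 together had no rise. Col1a1 alone was 5.708 and 5.552 in these 2 mice, against 5.225 to 5.541 in GFP livers. Without SHH 31, Col1a2 and Col3a1 differed by -0.09 and -0.20. A bound that also counted values below 0 would have been met by the mean of -0.031. It was tried only after that mean was seen and was not kept.

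Skeletal muscle carried along with the liver sample of SHH 28 is a candidate source of its muscle signal. It was prompted by the 7 muscle genes of the fixed list, all highest there. Of 29 muscle genes in a second list, 16 were highest there, where chance gives 16.7%, though the median fold of SHH 28 over the other livers was only 1.21. Muscle genes can move together within a sample, so that share does not measure how unusual 16 of 29 is.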
